A study of Homo sapiens with 9 samples.

How the data were processed

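The 9 samples were ATAC-seq libraries of SK-N-MC cells in 3 groups of 3 replicates: shScramble, shCHD4#1 (hairpin 1) and shCHD4#2 (hairpin 2), each after 48 h with 100 ng/ml doxycycline. Per the labels, 100000 SK-N-MC cells were mixed with 100 Drosophila S2 cells before tagging. The labels call the replicates biological. Groups were taken from the labels.

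Per the submitters' processing notes, the authors used Trimmomatic 0.36, FastQC 0.11.7, BWA, SAMtools 1.9 and deepTools 3.2.1, with the builds GRCh38 and dm6. The peak caller and its settings are not given in the sources used here, nor is any shift of read ends for the cut of Tn5 or any use of the Drosophila spike-in. Spike-in scaling could change the number of regions called per list and was not applied here. The deposited lists, 1 per group, carry in their deposited name that of ChIP-R, a program that combines peak lists of replicates, and no replicate number. They are filed under replicate 1 of each group, which leaves open that a list holds that replicate alone. They were treated as combined lists of the group, which is an inference. Each deposited region has a score from the authors, a whole number within its list. It also has a second authors' value, likewise treated as a score with no stated unit: 392, 396 and 399 regions, in the order above, have a negative value there. Of these, 376 have identical coordinates in all 3 lists, and the widest spans 18.7 Mb. Each region further has a p-value and a q-value from the authors, and the lists are sorted by the p-value. These values were used only to rank or filter regions within a list. The lists give no read counts, so depth per sample and the precision it gives are unknown. A deeper or more leniently called library would list more weak regions, and nothing in the lists allows a correction for that.

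Every region on chromosomes 1 to 22 and X was kept, 85775, 122869 and 83241 in the order above. Of these, only 1314, 1803 and 1369 had an authors' q of at most 0.05. Regions overlapped when they shared at least 1 bp. The 3 lists were merged into regions that share no base, and each merged region received 1 of 7 presence patterns. Gained with both means in both hairpin lists and not in shScramble, and lost with both means in shScramble only. The number lost with both was set beside the number expected from independent losses (n1 × n2 / N over the merged regions with a control region). No such number is given for gains, since each merged region without a control region is in a knockdown list by construction. Both numbers were set beside 100 random exchanges of the list names within each merged region, which treats the lists as equally long. Shares have 95% Wilson intervals, which cover counting error only and treat neighbouring regions as independent. No test between groups was possible with 1 list per group, so no replicate was left out in turn.

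Genes were 19974 protein-coding genes of the RefSeq table for the patch release of GRCh38 used here, the build of the lists. The table gives the start and end of each gene but no strand, exons or sequence. The plan made before the data were examined used transcription start sites; windows of 1 kb around either end of a gene replaced them, and a gene's locus is the gene with 5 kb on both sides, in place of 5 kb upstream. Exon and intron classes, the share of regions with GGAA repeats and 17 sequence motifs were planned and are not analysed here. Per gene, the log2 ratio of region number was computed with 1 added to both numbers, which understates the change at genes with few regions. The median and mean over each of 20 gene lists were placed among 10000 random lists of the same size, matched on 10 classes of shScramble region number and 5 classes of locus length. Some lists share genes, and neighbouring genes share regions.

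The named genes follow a rule fixed before the data were examined: CHD4, NR0B1, NKX2-2 and CCND1; up to 4 genes per list with the largest mean change in region number over both hairpins; the 10 genes nearest to the most gained and to the most lost regions, within 100 kb of a gene end; the 10 genes without a shScramble region that had the most gained regions; and the 5 best-ranked gained and lost regions. Some genes that the rule names are not reported here. The genes nearest to a region need not be regulated by it.

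Overlaps and patterns were tested on simulated regions: 8000 of 8000 overlaps and 5000 of 5000 patterns were recovered. For the gene list comparison, region numbers of 19974 genes were simulated with 10 changed and 100 unchanged lists, each simulated list being counted once per hairpin. Changed genes came only from loci with several control regions, unchanged genes had equal expected numbers in all lists, and only medians were scored. The simulation therefore does not show how well changes are found by means or where medians are 0. At a fold of 1.5, 10 of 10 changed lists and 6 of 100 unchanged lists lay outside the central 95%; at a fold of 2.0 these were 10 of 10 and 1 of 100. Alternatives fixed beforehand were an authors' p of at most 0.05, the best 20000 regions per list, joining regions within 200 bp, at least 50% of a region covered, presence at a p of at most 0.05 with absence at any score, every sequence in the lists, gene-end windows of 500 bp and 2.5 kb, loci extended by 50 kb, 5 added to region numbers, and unmatched random lists. Added after the data were seen were leaving out regions with negative values or wider than 20 kb, region midpoints at gene ends, the mean of a gene list, and the strict comparison for gene-end shares. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.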

Results

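Accessible chromatin was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in SK-N-MC cells, an established Ewing sarcoma cell line. The cells carried doxycycline-inducible short hairpin RNAs and were treated for 48 h with 100 ng/ml doxycycline. A non-targeting hairpin (shScramble) served as the control. The other 2 groups carried hairpins against CHD4, the ATPase of the NuRD chromatin remodelling complex: shCHD4#1, called hairpin 1 here, and shCHD4#2, called hairpin 2. Each group had 3 biological replicates, which made 9 samples. The deposited data analysed here were 3 lists of accessible regions, 1 per group, each filed under replicate 1 of its group and treated here as the combined list of its 3 replicates, which is an inference. With 1 list per group there was no spread between replicates to compare a difference with, and no difference between groups could be tested. Read depth was unknown. The 95% Wilson intervals given with shares cover counting error only.

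The comparison of each hairpin with shScramble asks how silencing of CHD4 changes chromatin accessibility. At the CHD4 locus itself (GRCh38, chromosome 12, 6570082 to 6607379), counted with 5 kb on both sides, 6 regions were listed with shScramble, 9 with hairpin 1 and 7 with hairpin 2. Region lists do not show how far CHD4 was silenced. Loci of 3 genes activated by the EWSR1::FLI1 fusion of this tumour were also fixed beforehand. NR0B1, an orphan nuclear receptor, had 3, 3 and 4 regions in the same order. NKX2-2, a homeodomain factor, had 8, 5 and 4. CCND1, which encodes cyclin D1, had 4, 5 and 6. At least 1 end of each of these 4 genes was covered in every list.

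On chromosomes 1 to 22 and X, 85775 regions were listed with shScramble, 122869 with hairpin 1 and 83241 with hairpin 2. Hairpin 1 thus listed 43.2% more regions than shScramble, and the number with hairpin 2 differed from shScramble by -2.95%. The hairpins also lay on opposite sides of the control in bases covered. Without regions wider than 20 kb or with a negative authors' value, 141 Mb was covered with shScramble, 199 Mb with hairpin 1 and 103 Mb with hairpin 2. At 23687 places with exactly 1 region in each list, the median width was 1520 bp with shScramble, 1490 bp with hairpin 1 and 1110 bp with hairpin 2. Hairpin 2 had the narrower region at 74.5% of these places. Of the shScramble regions, 77.4% (Wilson 77.1 to 77.6) shared at least 1 bp with a hairpin 1 region and 64.3% (64.0 to 64.7) with a hairpin 2 region. Regions absent from shScramble made up 44.9% (44.6 to 45.2) of the hairpin 1 list and 30.5% (30.2 to 30.8) of the hairpin 2 list. Well-ranked control regions were mostly kept. Of those with an authors' p of at most 0.05, 96.1% overlapped a hairpin 1 region of any score and 95.8% a hairpin 2 region. Most listed regions did not reach an authors' q of at most 0.05. Those that did numbered 1314 with shScramble, 1803 with hairpin 1 and 1369 with hairpin 2.

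Merging the 3 lists gave 130785 regions, of which 43447 were present in all 3. There were 13108 regions gained with both hairpins and 13772 lost with both. A further 37904 were listed with hairpin 1 only and 7109 with hairpin 2 only. Regions absent with hairpin 2 only numbered 11919, and those absent with hairpin 1 only 3526. If losses with each hairpin fell independently over the 72664 merged regions with a control region, 6116 would be lost with both, and the observed number was 2.25 times that. Both comparisons use the same control list, which by itself can raise the number lost with both. Low-ranked regions were also lost more often, which can raise it too. In the median, regions lost with both ranked at the 69.1% point of the shScramble list, against 30.2% for regions in all 3 lists. Exchanging the list names at random within each merged region, 100 times, gave a mean of 9503 gained with both (range 9287 to 9712) and 19603 lost with both (19223 to 19919). The exchange treats the lists as equally long, while 37904 regions were listed with hairpin 1 only against an exchange mean of 19591. List length can therefore contribute to these differences, and the exchange does not separate it from an effect of the hairpins. Of the hairpin 2 regions absent from shScramble, 62.0% (61.4 to 62.6) overlapped a hairpin 1 region absent from shScramble. Of all hairpin 2 regions, 83.2% (82.9 to 83.4) overlapped a hairpin 1 region.

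**Figure D1:**
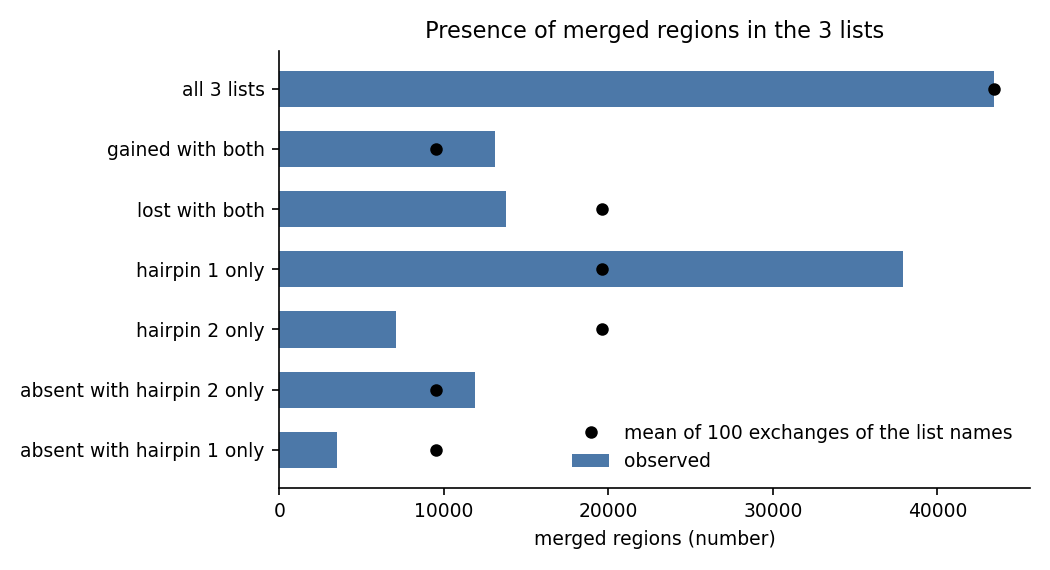
Number of merged regions (x axis) in each of the 7 presence patterns (y axis); bars are the observed numbers and dots the mean of 100 random exchanges of the list names within each merged region. Regions gained with both hairpins (13108) lie above the exchange mean of 9503, and regions lost with both (13772) below the mean of 19603; the exchange does not account for the longer hairpin 1 list.

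The gene nearest to the most regions gained with both hairpins was RXRA, the retinoid X receptor alpha (chromosome 9, 134326455 to 134440585), with 12; its locus had 17 regions with shScramble, 34 with hairpin 1 and 23 with hairpin 2. WNT7B, a Wnt ligand (chromosome 22, 45920366 to 45977162), was nearest to 11 and went from 4 regions with shScramble to 17 with hairpin 1 and 14 with hairpin 2. At KLF13, a Krüppel-like zinc finger factor (chromosome 15, 31326835 to 31435665), the numbers were 6, 19 and 14. All 3 of these genes had no covered end with shScramble and a covered end with both hairpins. RBFOX3, the neuronal splicing factor known as NeuN, had 24, 60 and 41 regions, and 16 gained regions lay in its locus. The Groucho corepressor TLE3 had 7, 11 and 12, the SUMO ligase-like coregulator ZMIZ1 had 15, 38 and 26, and the drug efflux pump ABCC1 had 7, 23 and 13. The numbers were 18, 35 and 23 at TSNARE1, 10, 18 and 15 at PRR5, a subunit of mTOR complex 2, and 19, 31 and 25 at DYSF, which encodes the muscle membrane repair protein dysferlin.

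Among genes with no shScramble region in the locus, the most regions gained with both lay at CIAO3, an iron-sulfur cluster assembly factor (0, 6 and 5 regions), NAT8L, which makes N-acetylaspartate (0, 6 and 4), and the adaptor gene SHC2 (0, 6 and 6), with 4 gained regions each. The other genes named by this rule had 3 gained regions each. Ties were broken by alphabet, so genes with as many gained regions can be left out. ARHGEF10 had 0, 9 and 3 regions, the calcium channel subunit CACNG6 0, 4 and 3, DENND6B 0, 6 and 5, the guanylate-binding protein gene GBP5 0, 5 and 3, and GRIFIN 0, 5 and 5. The drug-metabolising cytochrome P450 gene CYP2C19 had 0, 3 and 3 and no covered end in any list. The 5 gained regions named here have the best ranks when each is judged by the worse of its ranks in both knockdown lists. The first of them (chromosome 17, 82367121 to 82369040), number 110 with hairpin 1 and 572 with hairpin 2, lay in no protein-coding gene, 3684 bp from an end of UTS2R, the urotensin receptor gene. The next (chromosome 19, 6826391 to 6830030) lay inside VAV1, a guanine nucleotide exchange factor of blood cells. The others were at GTF2IRD2B (chromosome 7, 75092931 to 75093140), 62056 bp from an end of FAM53A (chromosome 4, 1511611 to 1512400) and 32607 bp from an end of PPIAL4F (chromosome 1, 144559301 to 144561270). GTF2IRD2B and PPIAL4F have near-identical copies elsewhere, so reads there could have been placed in either copy. Regions gained with both ranked at the 41.6% point of the hairpin 1 list and the 60.5% point of the hairpin 2 list in the median, counted from the best. Requiring an authors' p of at most 0.05 with both hairpins and no shScramble region at any score left 301 of them.

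Of the 10 genes nearest to the most regions lost with both hairpins, 5 lie on the long arm of chromosome 8. NSMCE2, a SUMO ligase of the SMC5/6 complex (125091860 to 125367120), was nearest to 13 of them and had 43 regions with shScramble, 36 with hairpin 1 and 22 with hairpin 2. ATAD2, a bromodomain ATPase (123319850 to 123416350), was nearest to 10 and had 16, 5 and 5 regions. ASAP1, an ARF GTPase-activating protein, had 76, 65 and 52. EFR3A had 17, 13 and 6, and ENPP2, which encodes autotaxin, had 12, 10 and 3. Of the others, the polarity gene PARD3 had fewer regions with each hairpin (21, 17 and 10). SV2B, which encodes a synaptic vesicle protein, had 15, 15 and 9. MED13L (17, 19 and 15) and the cadherin gene CDH12 (15, 26 and 11) had more regions with hairpin 1 than with shScramble and fewer with hairpin 2. An end of CDH12 was covered with shScramble and with neither hairpin. The stretch from ENPP2 to EFR3A, 12.5 Mb long, held 1191 regions with shScramble, 1177 with hairpin 1 and 928 with hairpin 2, which is 0.988 and 0.779 times the control number, against 1.43 and 0.970 times over all chromosomes. There, 26.7% (23.9 to 29.6) of the merged regions with a control region were lost with both, against 18.9% (18.6 to 19.1) elsewhere. The stretch was bounded by genes chosen for their lost regions, which by itself can raise its share. Among 32 bins of 10 Mb with at least 400 such regions, a limit chosen after the data were seen, chromosome 8 from 120 to 130 Mb (25.7%) and from 130 to 140 Mb (25.0%) had the highest shares, and the next was 20.5%. Bins with fewer regions reached 33.0%.

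The best-ranked region lost with both (chromosome 1, 224355791 to 224357190) overlapped CNIH4, a cargo receptor gene, 312 bp from a gene end, and was number 2786 in the shScramble list. The next ones overlapped KDM2B, a histone demethylase gene (chromosome 12, 121442911 to 121443600), and lay 80997 bp from an end of PRSS58 (chromosome 7, 142338321 to 142339790) and 12021 bp from an end of DCAF12 (chromosome 9, 34074081 to 34074650). The last of the 5 overlapped the helicase gene DHX37 (chromosome 12, 124988931 to 124990100). Lost regions ranked low: 80.2% lay past the middle of the shScramble list, and 67 had an authors' p of at most 0.05. The median distance from a lost region to the nearest region of either hairpin was 1800 bp, and from a gained region to the nearest shScramble region 6110 bp. Both hairpin lists together hold more regions than the shScramble list, which shortens the first distance, so these distances cannot be compared directly.

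Regions gained with both hairpins lay at gene ends more often than regions lost with both. Within 1 kb of an end of a protein-coding gene lay 18.8% (18.2 to 19.5) of regions gained with both and 7.99% (7.55 to 8.46) of those lost with both, against 27.7% (27.3 to 28.1) of regions in all 3 lists. Of 19974 protein-coding genes, 1329 had an end covered with both hairpins and not with shScramble, and 285 had the reverse. Over regions of any score the difference followed the hairpin 2 list. The share was 19.5% (18.6 to 20.4) in regions listed with hairpin 2 only and 7.43% (7.17 to 7.70) in those with hairpin 1 only. Outside the regions common to all lists, 19.1% (18.6 to 19.6) of merged regions in the hairpin 2 list and 7.91% (7.70 to 8.12) of those not in it lay at a gene end. For the hairpin 1 list these shares were 10.2% (9.93 to 10.4) and 12.9% (12.5 to 13.4). Over whole lists the gene-end share was 20.3% with shScramble (17421 regions), 17.1% with hairpin 1 (21045) and 22.4% with hairpin 2 (18682). In the strictest comparison, presence at an authors' p of at most 0.05 and absence at any score, the order turned: 27.9% (23.1 to 33.2) of 301 gained and 43.3% (32.1 to 55.2) of 67 lost regions lay at gene ends. There the share did not follow the hairpin 2 list: it was 26.4% (19.9 to 33.98) of 148 regions absent with hairpin 2 only and 52.5% (43.6 to 61.3) of 118 absent with hairpin 1 only, so both patterns with a hairpin 1 region had the lower shares. The reference gave no strand, so both ends of each gene stand in for the start site.

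**Figure D2:**
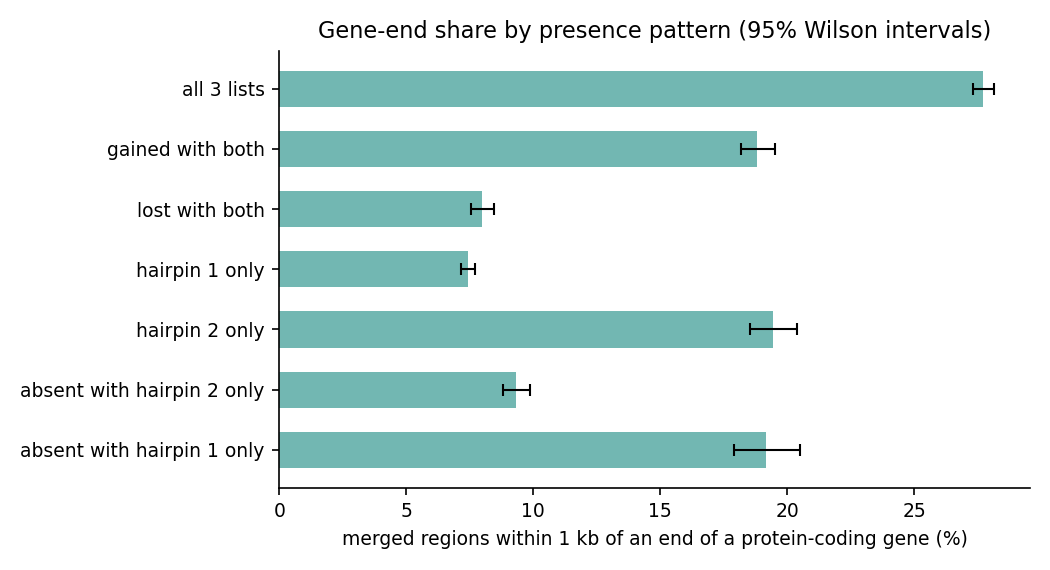
Share of merged regions within 1 kb of an end of a protein-coding gene (x axis, %) by presence pattern (y axis), with 95% Wilson intervals as error bars. The 3 patterns that include hairpin 2 without being in all lists lie between 18.8% and 19.5%, and the 3 without hairpin 2 between 7.43% and 9.33%.

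Counted over gene loci, 5026 genes (25.2%) had more regions with both hairpins than with shScramble and 2588 (13.0%) had fewer. The median log2 ratio of region number, with 1 added, was 0.17 over all genes with hairpin 1 and 0 with hairpin 2, so the 20 gene lists fixed beforehand are placed among 10000 random lists of the same size, matched on the number of shScramble regions and on locus length. The percentiles describe these lists and are not tests. Of the 40 medians, 6 lay outside the central 95% of random lists. Without ties 2.0 would by chance. However, 26 of the medians were 0 and many random medians were too, so the chance number for these lists is not known. With hairpin 2, 18 of the 20 medians were 0, so the mean, added after the data were seen, is given as well; 15 of 40 means lay outside. These calls depended on the regions used. With an authors' p of at most 0.05, and also with the best 20000 regions, none of the 6 medians and 4 of the 15 means still lay outside on the same side; with loci extended by 50 kb these numbers were 1 and 9.

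Developmental transcription factors and muscle genes had means above the central 95% of random lists with both hairpins. Of 61 developmental transcription factors, 26 had more regions with both hairpins and 5 fewer, and 12 gained a covered gene end with both while 3 lost it. The list's median stood at percentile 99.9 with hairpin 1 and 49.99 with hairpin 2, and its mean at 98.5 and 99.9. GATA6, an endoderm and heart factor that is also in the liver and gut list, had 0 regions with shScramble, 2 with hairpin 1 and 3 with hairpin 2. NEUROG2, a proneural factor, had 0, 1 and 4, OLIG2, of oligodendrocytes, 0, 2 and 2, and BARX1, a stomach homeobox gene, 0, 3 and 1. Of 42 skeletal and cardiac muscle genes, 16 had more regions with both and 0 had fewer. The median stood at percentile 99.7 with hairpin 1 and 49.7 with hairpin 2, and the mean at 99.9 and 97.8. Troponin T3 (TNNT3) had 0, 7 and 2 regions, tropomyosin 2 (TPM2) 0, 3 and 3, LDB3 of the Z-disc 3, 7 and 10, and TNNC2 1, 3 and 4. With regions of an authors' p of at most 0.05, the mean excess over random lists of the developmental factors was -0.083 with hairpin 1 and -0.13 with hairpin 2 on the log2 scale, and that of muscle genes -0.081 and -0.15. With hairpin 2 these means lay below the central 95% of random lists (percentiles 0.785 and 1.11), and with hairpin 1 inside it (7.34 and 13.7).

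NuRD subunits and apoptosis genes stood above random lists with hairpin 2. Of 15 NuRD genes, 8 had more regions with both hairpins and 2 fewer. The median was at percentile 72.6 with hairpin 1 and 99.8 with hairpin 2, and the mean at 88.9 and 98.3. CDK2AP1 had 0, 9 and 1 regions, GATAD2A 7, 13 and 10, MTA1 4, 7 and 6, and the deacetylase gene HDAC2 4, 3 and 2. With regions of an authors' p of at most 0.05, the mean stood at percentile 99.8 with hairpin 1 and 99.3 with hairpin 2, although the median was then at 49.6 and 49.9. The NuRD mean lay inside the central 95% with the best 20000 regions (86.7 and 90.0), with loci extended by 50 kb (84.1 and 87.7) and without matching (78.7 and 93.5). The median excess with hairpin 2 was 0 with a p of at most 0.05, with the best 20000 regions and with extended loci. Of 31 apoptosis genes, 15 had more regions with both and 3 fewer, with the median at percentile 96.8 and 99.5 and the mean at 93.2 and 99.3. Survivin (BIRC5) had 0, 2 and 2 regions, TNFRSF10A, a TRAIL receptor, 0, 2 and 1, and BAD 4, 9 and 8. With hairpin 2, the apoptosis mean lay inside the central 95% with an authors' p of at most 0.05 (percentile 77.2), with regions joined within 200 bp (93.6), with loci extended by 50 kb (68.8) and without matching (95.1). The median excess was 0 in the first 3 of these settings and with the best 20000 regions.

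The medians of endothelial and of haematopoietic and lymphoid genes lay above the central 95% with hairpin 1 and inside it with hairpin 2; the difference between the hairpins was not tested. With hairpin 2 both medians were 0, like the typical random median, so their percentiles near 50 reflect ties. For 17 endothelial genes the median stood at percentile 99.4 with hairpin 1 and 50.2 with hairpin 2, and the mean at 98.6 and 86.9. Of these genes, 5 had more regions with both and 0 fewer. The tight junction gene CLDN5 had 0, 4 and 1 regions, and EGFL7 2, 8 and 5. With hairpin 1 the endothelial median excess was 0 with an authors' p of at most 0.05 and with the best 20000 regions. The mean excess turned to -0.20 (percentile 3.05) and -0.45 (percentile 0.005). With the best 20000 regions this mean thus lay below the central 95%. For 40 haematopoietic and lymphoid genes the median was at percentile 97.6 and 49.6, and the mean at 96.7 and 61.6. With hairpin 1 this median lay inside the central 95% with an authors' p of at most 0.05 and with the best 20000 regions (excess 0 in both), with joined regions (percentile 87.5), with extended loci (95.6), with 5 added to each number (94.6) and without regions over 20 kb or with negative values (96.9). The B cell receptor gene CD79B had 0, 3 and 2 regions, and the myeloid factor gene SPI1 2, 7 and 4. The medians of the 44 neuronal genes lay inside the central 95%, at percentile 97.3 and 51.5, with GRIN1, an NMDA receptor subunit, at 4, 14 and 12 regions, ELAVL3 at 1, 5 and 4, and the sodium channel gene SCN1A at 5, 2 and 1. For the 39 HOX genes the median stood at 95.5 and 52.6 and the mean at 99.3 and 86.0. HOXA3 had 6, 19 and 14 regions and HOXA13 3, 1 and 1. The HOX mean with hairpin 1 lay inside the central 95% with an authors' p of at most 0.05 (percentile 56.6), with the best 20000 regions (77.8), with joined regions (85.3) and without matching (56.1). HOX loci adjoin each other and share regions.

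Of 45 genes activated by EWSR1::FLI1, 11 had more regions with both hairpins and 7 fewer. The median stood at percentile 52.8 with hairpin 1 and 57.0 with hairpin 2, and the mean at 86.0 and 98.3. The mean excess with hairpin 2 turned to -0.080 (percentile 14.1) with regions of an authors' p of at most 0.05, and the mean lay inside the central 95% with the best 20000 regions (91.3), with extended loci (77.5) and without matching (86.0). ID2 had 1, 6 and 5 regions, GSTM4, with a known GGAA repeat that the fusion binds, 1, 4 and 3, BCL11B 5, 15 and 8, and the telomerase gene TERT 0, 4 and 0. Of 40 genes repressed by the fusion or typical of mesenchyme, 11 had more and 6 fewer, with the median at percentile 73.9 and 50.7. The mean stood at 42.4 and 23.9. With hairpin 1 this mean lay below the central 95% with an authors' p of at most 0.05 (2.11) and with the best 20000 regions (1.065). ZEB1 had 0, 1 and 2 regions, COL6A3 and LUM each 1, 0 and 0. Of 37 DNA damage response and repair genes, 3 had more and 4 fewer, with the median at 8.13 and 55.8 and the mean at 1.77 and 10.0. MRE11 had 1, 4 and 4 regions, the checkpoint kinase gene CHEK1 2, 1 and 1, and XRCC3 5, 6 and 1. With regions of an authors' p of at most 0.05, the repair mean excess turned to 0.048 with hairpin 1, at percentile 71.1. Of 26 p53 targets, 5 had more and 6 fewer, with the median at 25.9 and 61.5.

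In the other lists the medians lay inside the central 95% with both hairpins. Of 35 cell cycle genes, 7 had more regions with both hairpins and 5 fewer (percentiles 27.5 and 51.5). AURKA had 2, 0 and 1 regions and TYMS 1, 2 and 4. The cell cycle mean with hairpin 1 stood at percentile 24.4. It lay above the central 95% with an authors' p of at most 0.05 (99.0) and with the best 20000 regions (99.3). Of 45 ribosomal protein genes, 12 had more and 13 fewer (43.3 and 53.8), and an end of each of the 45 was covered in every list. Of 34 bone, cartilage and fat genes, 12 had more and 2 fewer (84.2 and 50.3); SOX9 had 0, 2 and 2 regions and PPARG 0, 2 and 1. Of 32 liver and gut genes, 9 had more and 5 fewer (76.3 and 49.3), with APOA1 at 0, 3 and 2. Of 40 interferon and innate immune genes, 8 had more and 5 fewer (33.5 and 49.7), with IRF7 at 0, 2 and 2. Of 34 germline and cancer-testis genes, 6 had more and 1 fewer (34.9 and 49.7), although the mean stood at percentile 1.55 with hairpin 2; without matching it stood at 37.2, and with loci extended by 50 kb its excess turned to 0.11. MAEL had 0, 3 and 1 regions. Of 390 olfactory receptor genes, 16 had more and 9 fewer, and their mean lay below every random list with both hairpins, at medians of 0. Of 477 ZNF genes, 92 had more and 60 fewer, and the mean was below every random list with hairpin 1 and at percentile 2.17 with hairpin 2. ZNF787 had 1, 11 and 8 regions. The ZNF mean with hairpin 1 lay inside the central 95% with an authors' p of at most 0.05 (percentile 5.14) and with the best 20000 regions (25.8). Without matching, the mean excess was 0.018 for olfactory receptor genes and 0.021 for ZNF genes with hairpin 2.

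**Figure D3:**
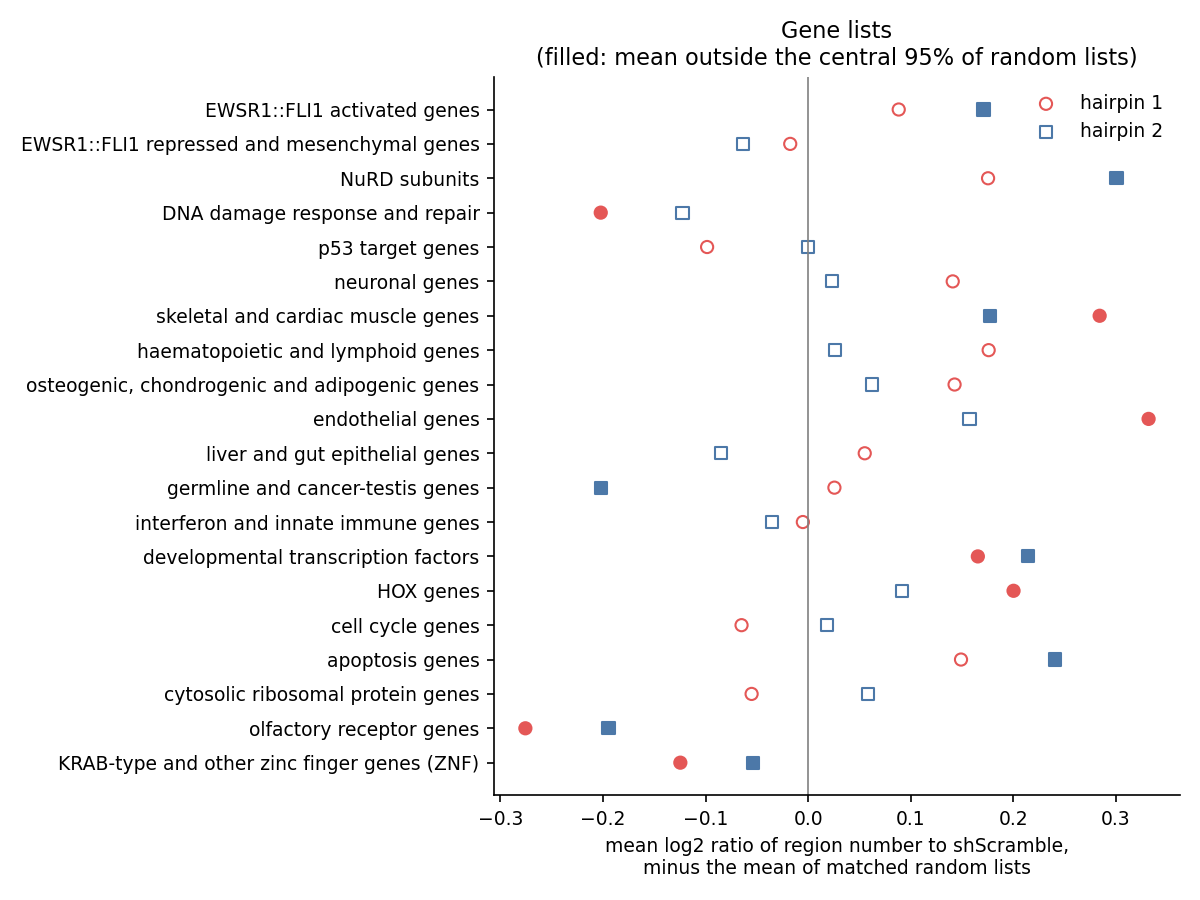
Mean log2 ratio of region number to shScramble over each gene list, minus the mean over matched random lists (x axis), for 20 gene lists (y axis); circles are hairpin 1, squares hairpin 2, and filled symbols lie outside the central 95% of 10000 random lists. Muscle genes and developmental transcription factors have filled symbols to the right with both hairpins, although with regions of an authors' p of at most 0.05 both means turn below the mean of random lists, outside the central 95% with hairpin 2. Olfactory receptor and ZNF genes have them to the left, although without matching the excess with hairpin 2 turns positive, inside the central 95%.

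By chromosome, gains with both hairpins outnumbered losses with both most on chromosome 19 (659 gained, 383 lost, ratio 1.72), followed by chromosome 16 (1.497), chromosome 22 (1.48) and chromosome 20 (1.41). The lowest ratios were on chromosome 13 (286 gained, 490 lost, ratio 0.584), chromosome 8 (0.680) and chromosome 4 (0.738). Relative to shScramble, hairpin 2 listed 1.13 times as many regions on chromosome 19 and 0.828 times as many on chromosome 13. Hairpin 1 listed between 1.30 times as many (chromosome 8) and 1.56 times as many (chromosome 16).

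**Figure D4:**
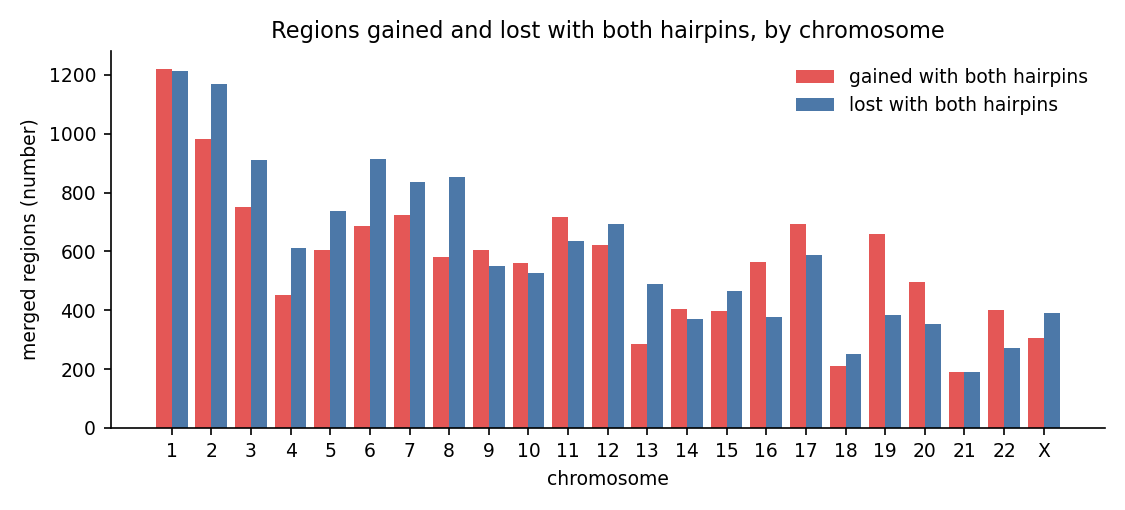
Number of merged regions (y axis) gained (red) and lost (blue) with both hairpins on each chromosome (x axis). Chromosome 19 has 659 gained and 383 lost regions, and chromosome 8 has 580 gained and 853 lost.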

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

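The tests in this part were chosen after the results were seen. With 1 list per group, the differences between the hairpins given here were not tested.

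The hairpins lay on opposite sides of shScramble in 3 measures, although both target CHD4. The number of regions differed from shScramble by 43.2% with hairpin 1 and by -2.95% with hairpin 2. Bases covered by regions of at most 20 kb with values above 0 differed by 41.2% with hairpin 1 and by -27.0% with hairpin 2. The gene-end share differed from shScramble by -3.18 percentage points with hairpin 1 and by 2.13 percentage points with hairpin 2. The number of regions at gene ends was above shScramble with both hairpins (21045 and 18682 against 17421). The lower share with hairpin 1 thus goes with its longer list. Not all 3 differences held under other settings. With an authors' p of at most 0.05 both hairpins listed more regions than shScramble (14673 and 10944 against 10781). Among the best 20000 regions both gene-end shares lay above that of shScramble (29.2% and 36.3% against 28.3%). Of the regions listed with hairpin 1 only, 75.1% ranked past the middle of that list and 0.393% had an authors' p of at most 0.05; for hairpin 2 only, these were 75.5% and 1.03%.

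The higher gene-end share of regions gained with both hairpins than of regions lost with both has 3 candidate explanations. Wider regions reaching more windows are argued against: with region midpoints the ratio of both shares was still 2.76. The composition of the hairpin 2 list accords with the values over regions of any score, since regions listed with hairpin 1 only had a share -0.56 percentage points from that of regions lost with both, while all patterns that include hairpin 2 had high shares. In the strict comparison it does not account for the shares: 27.9% gained and 26.4% absent with hairpin 2 only stood against 43.3% lost and 52.5% absent with hairpin 1 only, a split by the hairpin 1 list. CHD4 silencing, shared by both hairpins, stays open: among the best 20000 regions hairpin 1 exceeded shScramble by 0.875 percentage points, with overlapping Wilson intervals (28.5 to 29.8 against 27.7 to 28.9). With an authors' p of at most 0.05 hairpin 1 lay below it, 31.9% (31.1 to 32.6) of 14673 regions against 35.1% (34.2 to 36.0) of 10781, but these lists differ in length, and in each list the share falls as more regions are included. Without replicate lists or the degree of silencing this cannot be told apart from list composition. The difference therefore depends on the regions used and is not shown to be an effect of both hairpins.

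The lost regions on the long arm of chromosome 8 were weighed next, because 5 of the 10 genes nearest to the most lost regions lie there. For the stretch from ENPP2 to EFR3A, a lower copy number in both knockdown cultures stays open. Ranks and region numbers of hairpin 1 go opposite ways there. Ranks were compared in 3 ways. Of all merged regions with a control region, absent ones counted as worse, 31.3% (Wilson 28.4 to 34.3) in the stretch from ENPP2 to EFR3A ranked better with hairpin 1 than with shScramble, against 27.9% (27.5 to 28.2) elsewhere. For hairpin 2 these shares were 24.4% (21.8 to 27.3) and 28.9% (28.6 to 29.3). At places with 1 region in each list the share with hairpin 1 was 56.6% (49.6 to 63.3), against 43.4% elsewhere, but such places leave out lost regions. The best 1000 regions of each list had 37 in the stretch with shScramble, 69 with hairpin 1 and 28 with hairpin 2. A lower copy number would lower these ranks with hairpin 1. It would also lower the number of regions, and hairpin 1 listed 0.988 times the control number in the stretch against 1.43 times over all chromosomes. Chromosome 8 from 120 to 130 Mb had the lowest such ratio of 276 bins of 10 Mb with hairpin 1 (0.993). Its ratio with hairpin 2 (0.814) was number 39 from the lowest. From 130 to 140 Mb the ratio with hairpin 1 was 1.19. The long-arm bins from 50 to 120 Mb and from 140 to 150 Mb lay between 1.31 and 1.48 with hairpin 1. Over most of the arm, region numbers with hairpin 1 were thus near the 1.43 times over all chromosomes. With hairpin 2 the same bins ranged from 0.647 to 1.14. A larger number of control regions to lose stays open too. Chromosome 8 from 120 to 130 Mb had the most shScramble regions of the 276 bins (951). It also had the most merged regions with a control region (748). The genes were chosen by their number of lost regions, which more control regions can raise. In the stretch, 26.7% of merged regions with a control region were lost with both, above the 18.9% elsewhere and above the 20.5% of the next bin with at least 400 such regions, but bins with fewer regions reached 33.0%. The stretch was bounded by genes chosen for their lost regions, which by itself can raise its share, so this value does not decide. A difference in copy number in the other direction, or an effect of CHD4 silencing at these genes, was not tested and stays open.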

How the results depend on the processing

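No paired analysis was possible because each group has 1 list, treated here as combined, and no values per replicate. For the same reason no replicate was left out in turn. The GGAA repeat share and the 17 motifs were not run. Depth limits every count of regions here and is unknown. Leaving out regions with negative values or over 20 kb, the mean of a list, midpoints and the strict gene-end comparison were chosen after seeing the data. Of 95 comparisons of the main results with an alternative, 39 stayed within the interval, or within 1.5 times for counts, 55 moved and 1 reversed. Values stand in the order shScramble, hairpin 1, hairpin 2, or hairpin 1, hairpin 2.

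With an authors' p of at most 0.05, the lists held 10781, 14673 and 10944 regions; 69.0% and 61.6% of control regions were kept, and 49.4% and 39.5% of hairpin regions were gained. Gained with both were 2574 and lost with both 2427 merged regions. Gene-end shares were 47.3% in all 3 lists, 38.4% gained and 15.9% lost, a difference of 22.5 points. With the best 20000 regions, every list held 20000 by construction; 59.5% and 60.9% were kept, 41.4% and 39.3% were gained, 3658 merged regions were gained and 5575 lost with both, and 605 genes had an end lost with both. Gene-end shares were then 38.5%, 31.4% and 12.9%, a difference of 18.5 points. With equal list lengths the order of the hairpins in control regions kept turned. Losses with both outnumbered gains with both there, in the main lists and with 50% covered, and gains outnumbered losses with a p of at most 0.05, after joining and in the strict comparison below.

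Joining regions within 200 bp gave 11500 gained and 10392 lost regions, turning their order too, with 79.8% and 67.0% kept, 42.8% and 28.3% gained, and gene-end shares of 16.8% gained and 7.22% lost. Requiring 50% of a region covered gave 65.5% and 48.2% kept, 55.4% and 40.5% gained, and 12917 gained and 17898 lost regions with both. Presence at a p of at most 0.05 with absence at any score gave 96.1% and 95.8% kept, 8.44% and 6.11% gained, and 301 gained and 67 lost regions. Gene-end shares were then 48.5%, 27.9% and 43.3%, and the difference between gained and lost regions reversed to -15.4 points. The cause was not tested. Windows of 500 bp gave shares of 25.3%, 15.7% and 5.45%, windows of 2.5 kb 32.1%, 24.0% and 13.7%, and midpoints 16.4%, 12.03% and 4.36%. Leaving out regions with negative values or over 20 kb moved no main result, and counting every sequence, run for regions per group, moved none of those counts.

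Among gene lists, no median outside the central 95% of random lists changed sign, but 26 of the 40 medians were 0. With an authors' p of at most 0.05, and with the best 20000 regions, each of the 6 medians had an excess of 0. No sign change could therefore appear in these settings. Means outside the central 95% reversed as follows, as excess over random lists on the log2 scale. With a p of at most 0.05: EWSR1::FLI1 activated genes -0.080 (hairpin 2), repair genes 0.048 (hairpin 1), muscle genes -0.081 and -0.15, endothelial genes -0.20 (hairpin 1), developmental factors -0.083 and -0.13, and ZNF genes 0.0097 (hairpin 2). With the best 20000 regions: repair genes 0.022, muscle genes -0.075 and -0.15, endothelial genes -0.45 (hairpin 1), developmental factors -0.065 (hairpin 1), and ZNF genes 0.010 (hairpin 2). With loci extended by 50 kb, with hairpin 2: germline genes 0.11 and ZNF genes 0.025. Without matching, with hairpin 2: olfactory receptor genes 0.018 and ZNF genes 0.021. The cause was not tested. Of the other comparisons of lists, 474 kept their side of the central 95%, 46 no longer lay outside it, 16 newly did on the side of the main value, 4 newly did from a main value of 0, and 2 newly did with the opposite sign.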

Other observations

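In this part, the test without regions at gene ends was chosen after the result was seen; the other tests were written down before their results.

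Several of the named genes with gained regions and no shScramble region lie close to chromosome ends, which had no part in the plan. Some of these genes were named through ties broken by alphabet. CIAO3 (chromosome 16, 729765 to 740997) and SHC2 (chromosome 19, 416589 to 461033) lie near the ends of their short arms, as do NAT8L (chromosome 4, 2059327 to 2069089), GRIFIN (chromosome 7, 2474728 to 2476398) and ARHGEF10 (chromosome 8, 1823329 to 1958641). DENND6B (chromosome 22, 50309030 to 50327012) lies near the end of its long arm. Within 5 Mb of the outermost region listed on each chromosome lay 17.7% (Wilson 17.1 to 18.4) of regions gained with both hairpins, 9.42% (8.94 to 9.92) of those lost with both and 12.6% (12.3 to 12.9) of those in all 3 lists. The outermost listed region stands in for the chromosome end and can lie away from it where few regions are listed. On chromosomes 13 and 14, for example, the first 10 Mb bin with at least 100 merged regions with a control region started at 20 Mb. Over whole lists the share was 12.2% with shScramble, 13.7% with hairpin 1 and 14.7% with hairpin 2. With an authors' p of at most 0.05 it was 11.5% (10.9 to 12.1), 13.5% (12.9 to 14.0) and 14.5% (13.9 to 15.2). In the strictest comparison 56 of 301 gained regions (18.6%, 14.6 to 23.4) and 9 of 67 lost regions (13.4%, 7.23 to 23.6) lay there, with overlapping intervals.

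A hypothesis from these values is that chromatin near chromosome ends may be listed as accessible more often when CHD4 is silenced. The composition of the hairpin 2 list as the whole cause is argued against. Regions listed with hairpin 1 only lay there more often than regions lost with both, by 3.53 percentage points. The share with hairpin 1 only, 12.9% (12.6 to 13.3), was close to the 12.6% of all 3 lists, against 16.7% (15.8 to 17.6) with hairpin 2 only. Regions absent with hairpin 2 only had 9.75% (9.23 to 10.3), and those absent with hairpin 1 only 11.9% (10.8 to 13.0). A part played by the hairpin 2 list therefore stays open. A larger number of gene ends near chromosome ends is argued against as the whole cause, since without regions at gene ends gained regions still exceeded lost ones by 7.64 percentage points. The best 20000 regions of each hairpin lay there more often than those of shScramble (10.95%, 10.5 to 11.4). The shares were 13.4% (13.0 to 13.9) for hairpin 1 and 14.4% (14.0 to 14.9) for hairpin 2, the lower of them above shScramble by 2.48 percentage points. Both differences use the same shScramble list, so a low share in that list alone could give both. Also open are GC content, which is high near many chromosome ends and can shift with library amplification, and chance variation between cultures. Neither of these was tested, as no sequence was used and each group has 1 list.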
